A study of Mus musculus with 45 samples.

How the data were processed

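The series holds bulk RNA sequencing of pancreatic islets of Langerhans, the endocrine cell clusters that make insulin, glucagon and other hormones, from male and female mice of 3 inbred strains. C57BL/6J is a common laboratory strain, NZO/HlLtJ is an obese strain that is prone to diabetes, and CAST/EiJ is a wild-derived strain. Per the labels' protocols, mice received a control diet with 10% fat or a high fat, high sugar diet with 44% fat, both with fiber, from 6 weeks of age, and tissue was collected at 16 weeks. Libraries were made from polyadenylated RNA with the KAPA mRNA HyperPrep kit after an ERCC spike-in was added, and sequenced 150 bp paired-end on a NovaSeq to a target of 100 M read pairs, per the labels. The spike-in was not analysed here.

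The deposited matrix of estimated counts holds 22904 genes in 45 libraries. These estimated counts are not normalised, and 23.6% of the values are not whole numbers, and how the fractions arose is not given in the sources used here. No gene in this matrix has a count of 0 in more than 22 libraries. The aligner and the counting program are not given in the sources used here, and GRCm38 is the genome build named in the submitters' processing notes. Whether strain variants were allowed for is not given either, and differences between strains in counts depend on it. The authors also deposited a matrix of variance-stabilised values on a log2 scale for the same genes, and DESeq2 is named in the submitters' processing notes without its role. Gene symbols, Ensembl identifiers and GRCm38 coordinates came from the deposited annotation, in which 41 symbols occur more than once. Reads of near-identical genes, such as the Amy2a, Prss, Reg3, Hba and MHC class II families and the ribosomal protein pseudogenes, can be split differently by different counting programs, so values of single members are uncertain. Antisense and overlapping genes are uncertain too, since strand use in the counting is not given in the sources used here.

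Estimated counts were rounded to whole numbers. The total per library ranged from 57.2 to 110 M, with a median of 84.4 M. CPM are counts scaled to a library total of 1e6. A gene at 1 CPM rests on about the total in M times the composition factor of the library (TMM, 0.486 to 1.178) in counts. Libraries fell into 12 groups of strain, sex and diet, with 4 libraries in 9 groups and 3 libraries in 3 groups (CAST/EiJ males on 10% fat, and NZO/HlLtJ males on either diet). Replicate numbers follow the order of the series and pair nothing. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these libraries. Sample codes in the labels begin with 76, 80 or 89 in 14, 16 and 15 libraries, a number series that the labels do not explain. In NZO/HlLtJ, series 80 held only females on 10% fat and males on 44% fat, and series 89 only females on 44% fat and males on 10% fat. Series and diet are thus balanced over both sexes together but partly confounded within each sex and for the diet-by-sex interaction. Series and sex on 10% fat are partly confounded as well. The series was entered as a factor in an alternative model.

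The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation, the default expression filter over the 12 groups, robust estimation and Benjamini-Hochberg adjustment within each comparison, at an adjusted p under 0.05. The filter left 20306 genes. One model of the 12 groups held all 45 libraries, and contrasts gave 19 comparisons. These were the diet effect (44% against 10% fat) in each strain as the mean over the sexes and in each sex, the diet-by-strain and diet-by-sex interactions, the differences between strains on 10% fat as means over the sexes, and the difference between males and females on 10% fat as a mean over the strains. Every adjusted p of a gene below comes from this edgeR test unless another tool is named, standard errors (SE) were derived from the log2 fold change and its F statistic, and levels are CPM with TMM factors.

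Gene lists for 33 cell types and processes were fixed before the data were examined, as were the comparisons, the tests, the rule for naming genes and all alternatives but a pair that left out libraries after their counts were seen. The lists covered beta cell identity, dedifferentiation markers, genes normally repressed in mature beta cells, insulin granule and exocytosis genes, alpha, delta, and gamma and epsilon cells, acinar cells, the Reg family, duct cells, endothelial cells, fibroblasts with stellate cells and matrix, macrophages, lymphocytes and plasma cells, adipocytes, Schwann cells, red blood cells, MHC class II presentation, the cell cycle, the unfolded protein response, the antioxidant response, glycolysis, oxidative phosphorylation, glucose-responsive ChREBP targets, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation with PPAR targets, serotonin and prolactin receptor signalling, the interferon response, the inflammatory cytokine response, hypoxia, immediate early genes and the circadian clock. Each list was tested in each comparison, 627 tests in all, with camera (limma 3.58.1), which compares a list with all other genes, at its preset correlation of 0.01. The tests were repeated with a correlation estimated from the data and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. Adjusted p-values of lists were taken over the 33 lists of a comparison. Some genes stand in more than one list, and several markers of other cell types are also expressed by islet endocrine cells.

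Genes were named by rule. For mean diet effects and strain differences the rule took the 10 genes with the largest rises and the 10 with the largest falls among those past the threshold with an average log2 CPM of at least 1, and for other comparisons 5 and 5, without predicted genes known only by a clone or model number. It also took the 4 members of each list with the smallest p, and always Ins1, Ins2, Gcg, Sst, Ppy, Mafa, Ucn3, Slc2a2 and Aldh1a3, with Xist, Ddx3y, Kdm5d and Nnt as checks of the labels. Uty and Eif2s3y, further genes of the rule, were not analysed here.

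The procedure was tested on simulated counts with the real means, depths and dispersions, in which 200 genes changed by 1.5-fold or 2-fold in C57BL/6J and NZO/HlLtJ and 20 genes changed in CAST/EiJ. The changed genes were drawn only from well expressed genes, with an average log2 CPM of at least 1 and a minimum expected count in every group. Counts of different genes were drawn independently. The shares recovered therefore hold for such genes and not for weakly expressed ones. For the mean diet effect, edgeR recovered 74% of the 1.5-fold and 89% of the 2-fold changes in C57BL/6J, and 80% and 96% in NZO/HlLtJ, with 19987 genes tested. In CAST/EiJ it recovered 65% of the 1.5-fold changes. For single sexes the shares were 52% and 83% in C57BL/6J females, 51% and 82% in C57BL/6J males, 69% and 92% in NZO/HlLtJ females, and 41% and 94% in NZO/HlLtJ males. False calls of the mean effect were 14 of 177 in C57BL/6J, 10 of 186 in NZO/HlLtJ and 3 of 16 in CAST/EiJ. In single sexes they were 13 of 148 in C57BL/6J females, 16 of 149 in C57BL/6J males, 12 of 173 in NZO/HlLtJ females, 22 of 157 in NZO/HlLtJ males, 4 of 12 in CAST/EiJ females and 6 of 13 in CAST/EiJ males. These shares are above 5% in each case, and for the diet-by-sex interactions, where 0 genes changed, edgeR called 0 in C57BL/6J, 1 in CAST/EiJ and 1 in NZO/HlLtJ.

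Alternatives chosen before the data were examined were RLE size factors, total counts without a composition factor, no expression filter, the legacy quasi-likelihood method, the DESeq2 1.42.0 Wald test, limma-voom, limma-trend on the deposited log2 values, the number series as a factor, an acinar score as a covariate, models of single strains or pairs of strains, and leaving out each library in turn. Chosen after the counts were seen were models without 5 libraries that carried transcripts of another strain and without 3 libraries with high lymphocyte markers. The latter were C57BL/6J male 44% fat replicate 2, CAST/EiJ male 10% fat replicate 3 and CAST/EiJ male 44% fat replicate 1. For each comparison, up to 100 other splits of its samples were refitted to see how often as many genes were called.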

Results

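Islet RNA was sequenced from C57BL/6J, CAST/EiJ and NZO/HlLtJ mice of both sexes fed 10% or 44% fat, in 45 libraries of 57.2 to 110 M counts each. Groups held 4 libraries, except CAST/EiJ males on 10% fat and NZO/HlLtJ males on either diet, which held 3. Sex markers and Nnt matched the labels, and 5 libraries also carried transcripts of another strain. In CAST/EiJ females on 44% fat, replicates 1, 2 and 4 held markers of C57BL/6J at medians of 10.3%, 3.94% and 4.11% of its level. Only 2 of these 18 markers are absent in NZO/HlLtJ (median under 0.1 CPM), and they were at 9.79%, 0.995% and 3.88%. In replicate 2, 2 NZO/HlLtJ markers absent in C57BL/6J were at 2.25%, so its source strain is not settled. The other libraries with such transcripts were C57BL/6J female 44% fat replicate 2, with 2.43% of the NZO/HlLtJ level, and NZO/HlLtJ male 44% fat replicate 3, with 2.01% of the CAST/EiJ level and the highest Xist among males. Xist, which is transcribed from the inactive X chromosome, was at 531 to 1940 CPM in the 24 female libraries and at 0.0442 to 15.4 CPM in the 21 male libraries. Ddx3y, a Y-linked RNA helicase, was at 44.4 to 74.4 CPM in males and at most 0.0327 CPM in females. Nnt, a mitochondrial transhydrogenase whose gene carries a deletion in C57BL/6J, was at 26.2 to 35.6 CPM in the 16 C57BL/6J libraries and at 55.2 to 114 CPM in the other 29. Insulin transcripts made up 13.1 ± 1.21% of the counts in NZO/HlLtJ males on 10% fat (mean ± SD, n = 3) and 6.79 ± 2.49% on 44% fat (n = 3). In NZO/HlLtJ females they made up 10.6 ± 1.67% and 12.4 ± 1.2% (n = 4 each). Acinar transcripts, a measure of exocrine tissue, made up 5.74 ± 0.86% and 15.8 ± 5.5% of the counts in the same males, and 4.5 ± 3.6% and 7.42 ± 2.63% in the females.

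In NZO/HlLtJ islets on 44% fat, genes of mature beta cells fell, mostly in males, and genes of immune cells, fibroblasts, ducts, cell division and the interferon response rose. As a mean over the sexes (n = 7 per diet), the log2 level of Slc2a2, the glucose transporter of mouse beta cells (chromosome 3, 28697903 to 28731359, GRCm38), fell by 1.07 (SE 0.17, adjusted p = 8.83e-06). Ucn3, a maturity marker that beta cells secrete (chromosome 13, 3940688 to 3945349), fell by 1.18 (SE 0.17, adjusted p = 2.29e-06), and Slc30a8, the zinc transporter of insulin granules, fell by 1.01 (SE 0.13, adjusted p = 1.76e-07). The insulin genes gave -0.20 for Ins1 (SE 0.15, adjusted p = 0.322) and -0.24 for Ins2 (SE 0.14, adjusted p = 0.201). The Ins1 effect differed between the sexes as given below. For Ins2 the difference between the sexes lost its call without NZO/HlLtJ male 44% fat replicate 3 (-0.98, adjusted p = 0.0522). So did its fall in males (-0.60, adjusted p = 0.0532). Of 20306 genes tested, 7270 passed the threshold, 3762 higher and 3508 lower on 44% fat. Changes of at least 2-fold were mostly rises, with 1765 genes higher and 199 lower. With counts scaled to library totals alone, the median log2 fold change of all genes moved from -0.019 to -0.151, and 5081 genes were called, 2370 higher and 2711 lower. RLE gave 4160 higher and 2906 lower, DESeq2 4102 and 3024, and limma-trend 4195 and 2756.

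The beta cell identity genes fell in NZO/HlLtJ as a mean over the sexes, carried by the males (25 fell, median -1.03) more than by the females (4 rose and 4 fell, median -0.20). Of 26, 20 fell and 0 rose, or 20 and 0 when adjusted over the list alone, with a median log2 fold change of -0.65 (camera adjusted p = 2.4e-12, adjusted p = 0.14 with an estimated correlation, fry adjusted p = 2.5e-06). Among them were Trpm5, a cation channel of the insulin secretory response (-1.30, SE 0.16), Gipr, the receptor of the incretin GIP (-1.17, SE 0.15), and Pax6, an endocrine transcription factor (-0.70, SE 0.09). Of 22 genes normally repressed in mature beta cells, 20 rose and 0 fell (21 and 0 over the list alone), with a median of 0.97 (camera adjusted p = 2e-12, adjusted p = 0.15 with an estimated correlation). These included the cytoskeletal gene Zyx (0.93, SE 0.14), the ornithine aminotransferase Oat (0.78, SE 0.12) and the transcriptional repressor Rest (1.04, SE 0.18). Of 11 dedifferentiation markers 6 rose (7 over the list alone; camera adjusted p = 0.0014, adjusted p = 0.086 with an estimated correlation). Among them were the gut hormone gene Gast (2.68, SE 0.34, adjusted p = 1.11e-07) and the progenitor factor Sox9 (1.55, SE 0.39, adjusted p = 0.00193), which is also on the duct list. Bulk RNA does not show whether this list and the one before it rose in beta cells or in other cells. The hormone gene Cck (chromosome 9, 121489825 to 121495689) rose by 3.77 (SE 0.47, adjusted p = 1.19e-07), or by 5.04 without NZO/HlLtJ male 10% fat replicate 3. Of 24 insulin granule and exocytosis genes 8 fell, such as Rims2 (-0.56, SE 0.073), and 3 rose, such as the granule protein Chgb (0.82, SE 0.18). With library totals 7 fell and 1 rose. Over the list alone the numbers were 9 and 3 (camera adjusted p = 0.023, adjusted p = 0.64 with an estimated correlation, and adjusted p = 0.082 with an acinar score in the model).

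**Figure D1:**
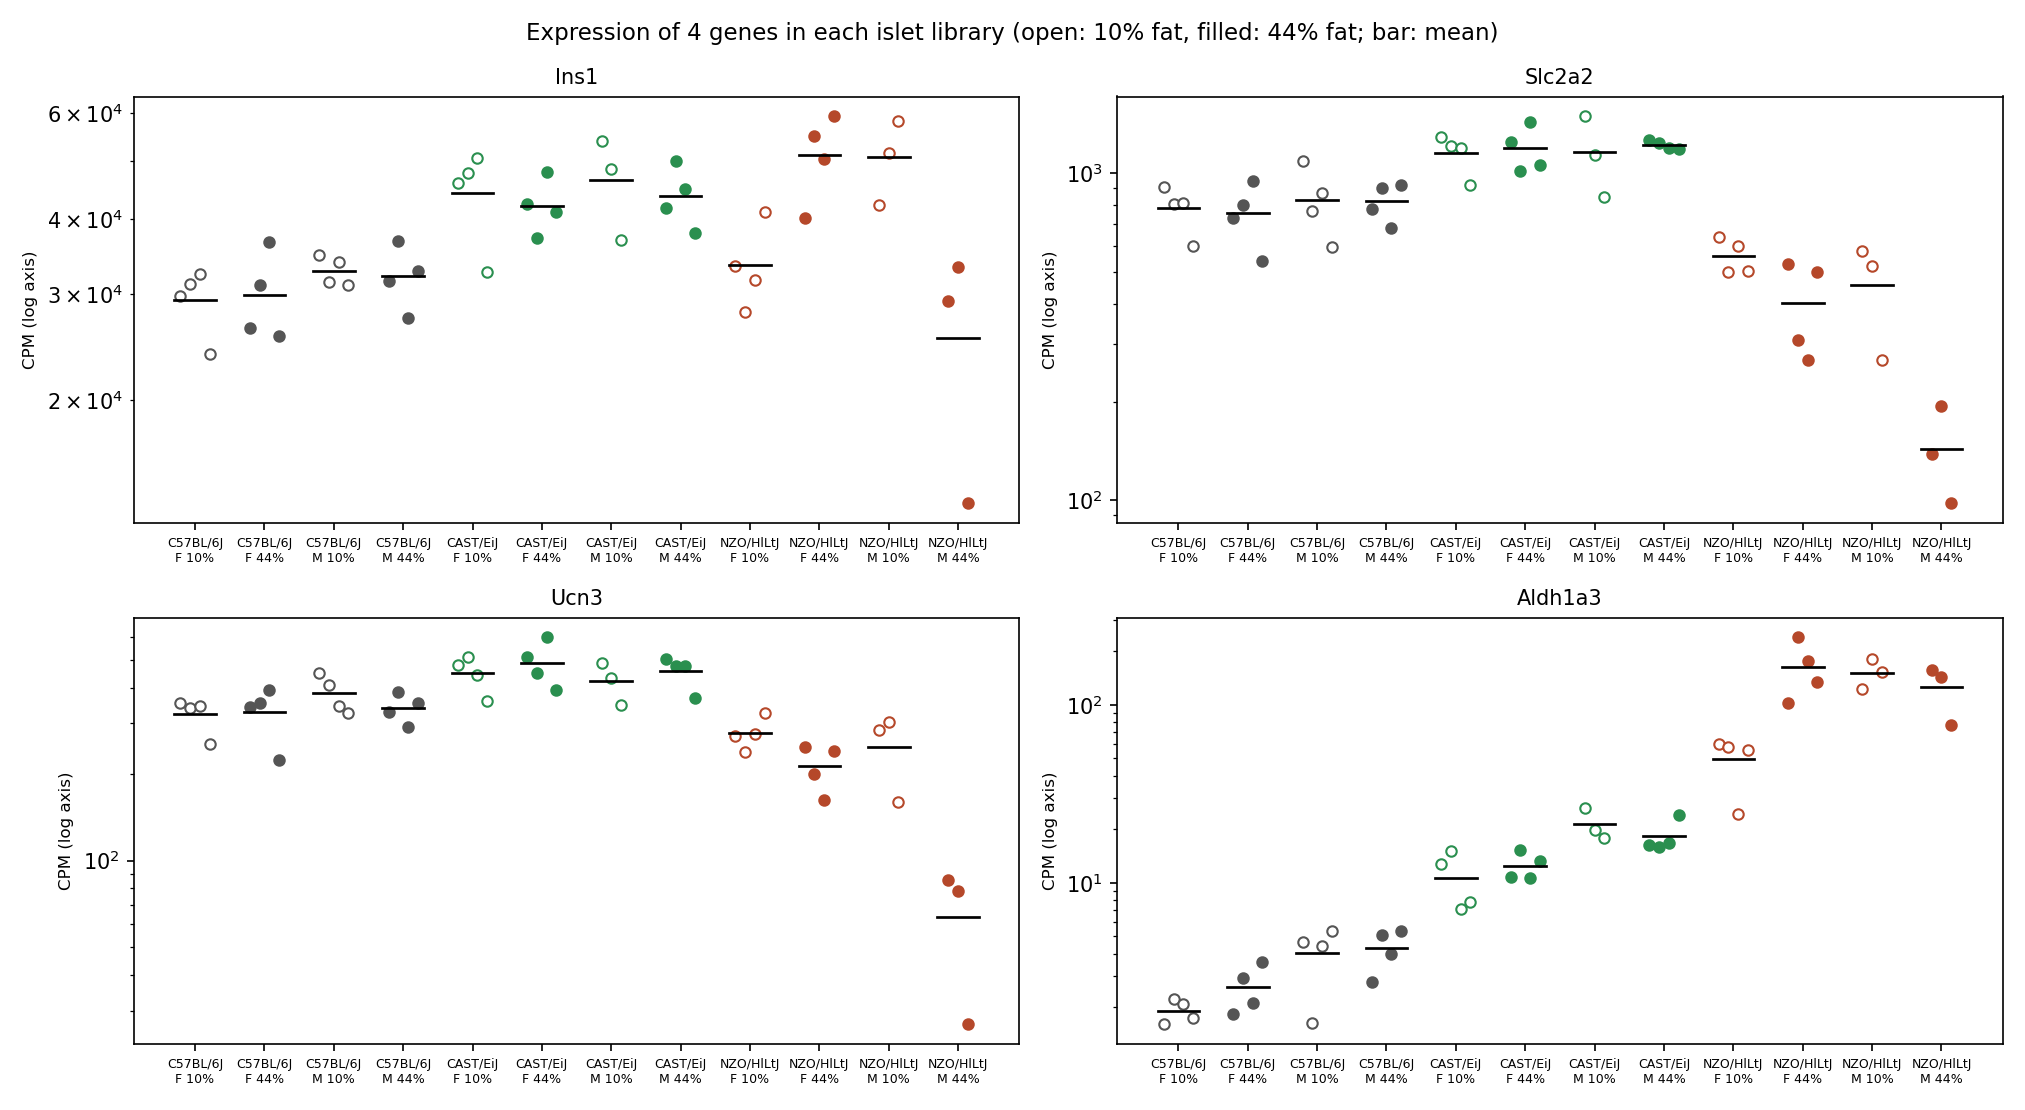
Levels of Ins1, Slc2a2, Ucn3 and Aldh1a3 in CPM on a log axis, with 1 point per library, for 3 strains, both sexes and both diets (10% and 44% fat). In NZO/HlLtJ males Ucn3 was at 250 ± 77.7 CPM on 10% fat and 63.5 ± 31.9 CPM on 44% fat (mean ± SD, n = 3 each).

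Immune, stromal and duct genes rose in NZO/HlLtJ on 44% fat. All 19 macrophage genes rose (19 over the list alone), with a median of 1.81 (camera adjusted p = 3.7e-21, adjusted p = 0.073 with an estimated correlation). They include the complement gene C1qc (1.97, SE 0.19, adjusted p = 6.26e-09) and the surface receptor Adgre1 (1.95, SE 0.2, adjusted p = 1.52e-08). All 10 genes of MHC class II presentation rose (10 over the list alone; median 1.98, camera adjusted p = 1.8e-10, adjusted p = 0.13 with an estimated correlation), such as the invariant chain gene Cd74 (1.90, SE 0.22). Of 16 lymphocyte and plasma cell genes 15 rose (16 over the list alone; median 2.75, camera adjusted p = 0.00013, adjusted p = 0.55 with an estimated correlation), such as the T cell kinase Lck (1.72, SE 0.37). Without NZO/HlLtJ male 44% fat replicate 3, 11 of them rose, and 8 without the 5 libraries that carried transcripts of another strain. All 20 genes of fibroblasts, stellate cells and matrix rose (20 over the list alone; median 1.26, camera adjusted p = 9e-15, adjusted p = 0.13 with an estimated correlation), such as Col6a3 (1.32, SE 0.18) and Mgp (1.24, SE 0.18). Of 14 duct genes 10 rose and 1 fell (11 and 1 over the list alone; median 0.88, camera adjusted p = 6.8e-05, adjusted p = 0.21 with an estimated correlation), such as the carbonic anhydrase Car2 (2.13, SE 0.3). Of 15 endothelial genes 9 rose (9 over the list alone; median 0.31, camera adjusted p = 0.0093, adjusted p = 0.6 with an estimated correlation), with 6 called without NZO/HlLtJ male 44% fat replicate 3 and 0 with counts scaled to library totals. Of 30 acinar genes 4 rose (2 over the list alone; median 1.10, camera adjusted p = 0.03, adjusted p = 0.81 with an estimated correlation), or 2 rose without NZO/HlLtJ male 44% fat replicate 3. With an acinar score in the model 6283 genes were called for the diet. The score is the mean log2 level of the same 30 acinar genes. Their own 4 rises and 17 falls in that model therefore do not measure a change of acinar genes.

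Cell division and interferon genes rose as well. Of 31 cell cycle genes 30 rose (30 over the list alone), with a median of 1.36 (camera adjusted p = 1e-25, adjusted p = 0.073 with an estimated correlation). Examples are the mitotic kinesin Kif11 (1.47, SE 0.15, adjusted p = 1.52e-08) and the replication helicase subunit Mcm5 (1.18, SE 0.14, adjusted p = 1.2e-07). Of 32 interferon response genes 31 rose (31 over the list alone; median 1.13, camera adjusted p = 3.2e-18, adjusted p = 0.13 with an estimated correlation). Among these were the nucleic acid sensor Zbp1 (2.65, SE 0.37) and the antiviral gene Oas1a (1.44, SE 0.19). Of 18 inflammatory cytokine genes 8 rose (8 over the list alone; median 1.04, camera adjusted p = 0.0017, adjusted p = 0.37 with an estimated correlation). These included the iron-binding protein gene Lcn2 (2.43, SE 0.47) and the adhesion molecule gene Vcam1 (1.93, SE 0.34). The acinar share moved with these groups in males, and macrophage transcripts summed to 144, 255 and 432 CPM in the NZO/HlLtJ male libraries on 10% fat and to 849, 935 and 1470 CPM on 44% fat.

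**Figure D2:**
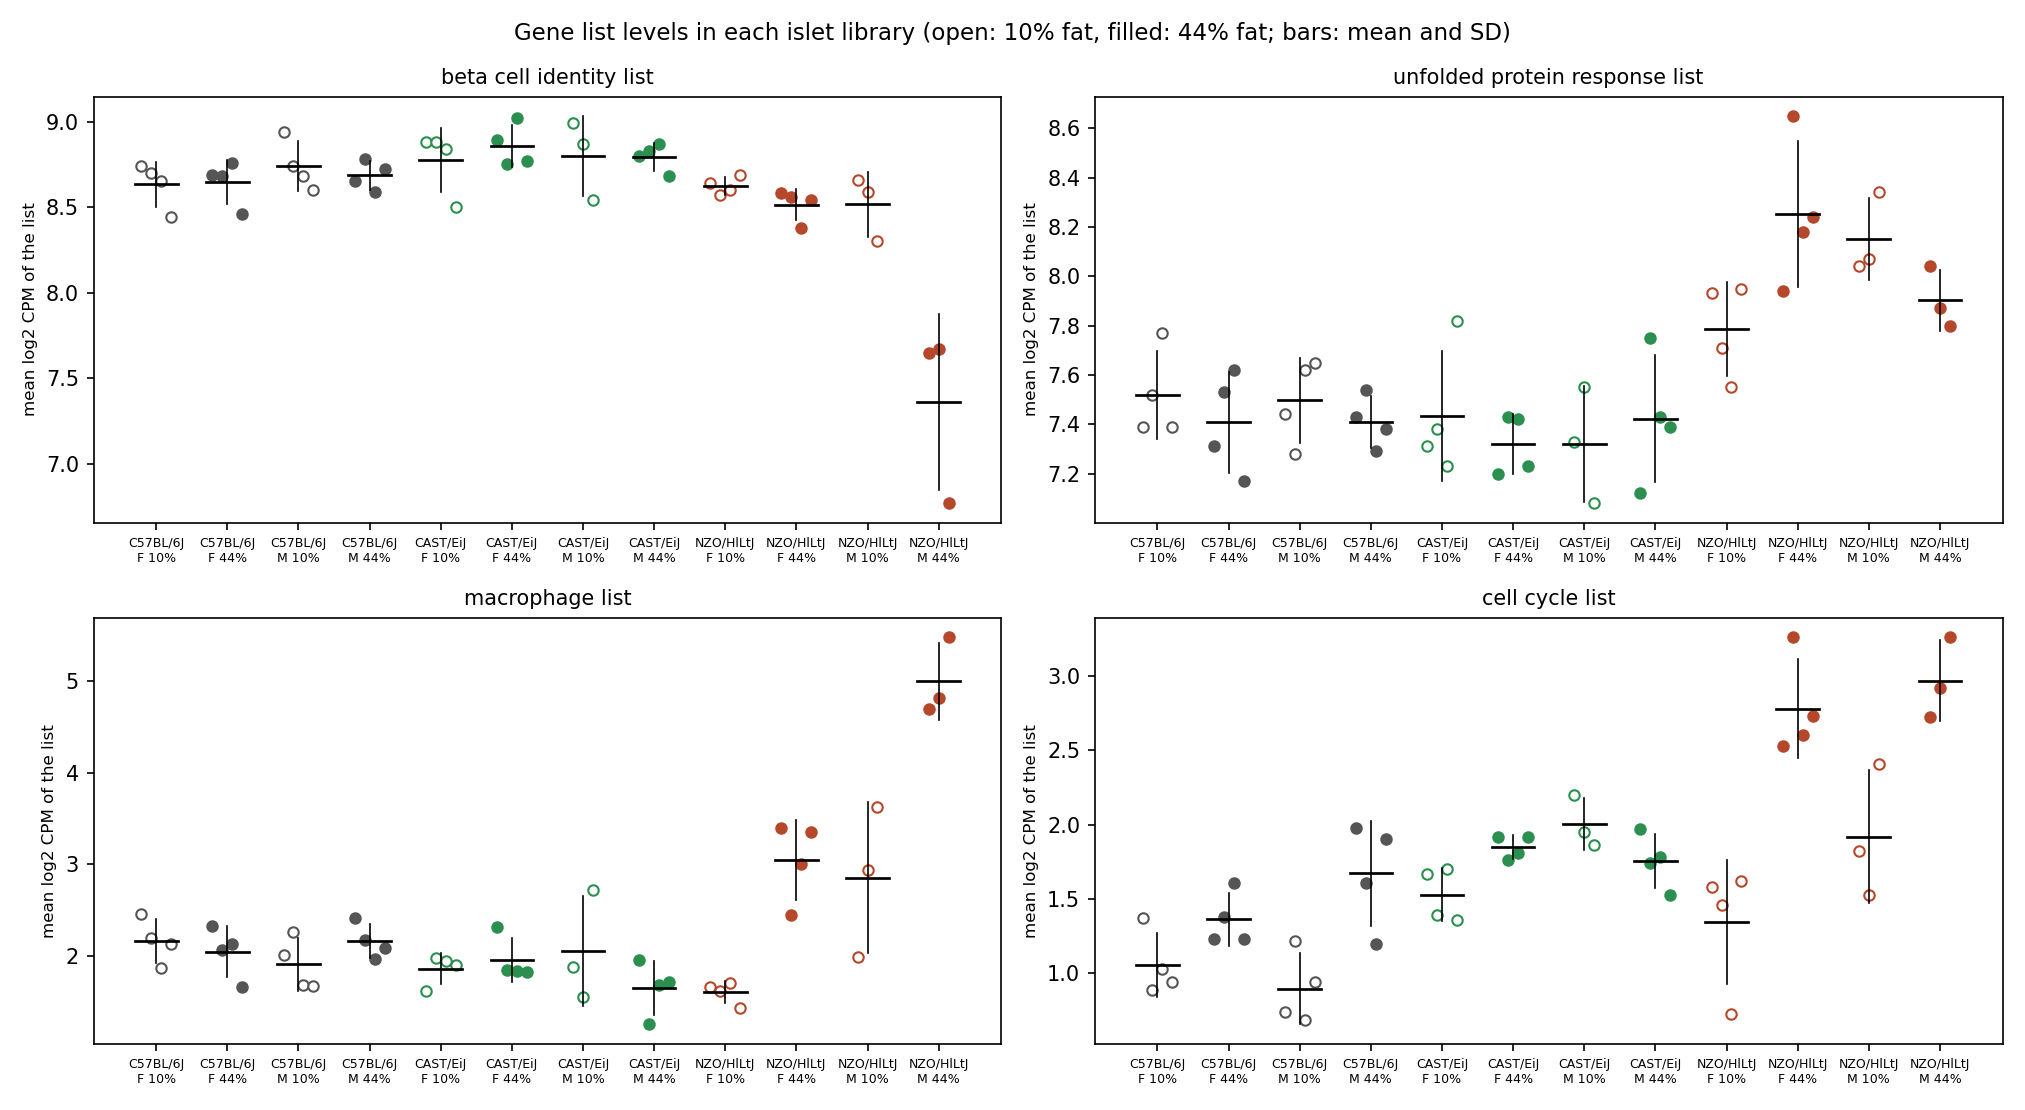
Mean log2 level of the genes of 4 lists (beta cell identity, unfolded protein response, macrophage and cell cycle), with 1 point per library, for 3 strains, both sexes and both diets (10% and 44% fat). All 19 macrophage genes rose in NZO/HlLtJ on 44% fat, with a median log2 fold change of 1.81 as a mean over the sexes.

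Metabolic genes in NZO/HlLtJ moved in both directions within their lists. The thioredoxin-interacting protein gene Txnip (1.26, SE 0.2, adjusted p = 6.12e-06) and its relative Arrdc4 (1.34, SE 0.19, adjusted p = 1.35e-06), both induced by glucose through ChREBP, rose. Mlxipl, which encodes ChREBP, fell by 0.92 (SE 0.18). Of 10 genes on the list of ChREBP targets 3 rose and 3 fell (camera adjusted p = 0.26, fry adjusted p = 0.0029), or 5 and 2 without NZO/HlLtJ male 10% fat replicate 3. Of 26 genes of fatty acid oxidation and PPAR targets 11 rose and 3 fell (camera adjusted p = 0.11, fry adjusted p = 0.045), such as the fatty acid transporter Cd36 (1.63, SE 0.35). Without NZO/HlLtJ male 44% fat replicate 3, 7 rose and 2 fell, and with library totals 5 and 2. Of 14 hypoxia genes 4 rose and 7 fell (camera adjusted p = 0.48, fry adjusted p = 0.046), with the vascular growth factor Vegfa down by 0.88 (SE 0.1, adjusted p = 1.07e-07). Of 16 glycolysis genes 5 rose and 3 fell (camera adjusted p = 0.86), such as the lactate dehydrogenase Ldha (1.05, SE 0.21) and the neuronal enolase Eno2 (-0.72, SE 0.069), or 3 and 2 with library totals. Of 15 antioxidant genes 3 rose and 4 fell (camera adjusted p = 0.86), including the quinone reductase Nqo1 (-1.43, SE 0.19). Without male 44% fat replicate 3 the antioxidant numbers were 2 and 1, and with library totals 1 and 2. Of 18 fatty acid synthesis genes 2 rose and 3 fell (camera adjusted p = 0.99), including the desaturase Fads2 (0.72, SE 0.11), or 3 and 6 without male 10% fat replicate 3. Among 16 circadian clock genes 4 fell (camera adjusted p = 0.076, fry adjusted p = 0.0029), including Clock (-0.44, SE 0.078), and 2 fell with an acinar score in the model. Among 9 genes of serotonin and prolactin receptor signalling 1 fell, the prolactin receptor gene Prlr (-0.82, SE 0.17; camera adjusted p = 0.27, fry adjusted p = 0.028), or 2 without either of those libraries.

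The remaining lists held few calls in NZO/HlLtJ, and single libraries or models moved them. Cholesterol synthesis had 0 rises and 4 falls among 25 genes (camera adjusted p = 0.86), oxidative phosphorylation 1 and 3 among 32 (camera adjusted p = 0.48), and the unfolded protein response 4 and 0 among 29 (camera adjusted p = 0.54). Without male 10% fat replicate 3 they had 2 and 6, 4 and 3, and 4 and 1, and without male 44% fat replicate 3 they had 0 and 2, 0 and 3, and 4 and 0. The unfolded protein response had 3 and 2 with the number series as a factor, and 2 and 0 with an acinar score. Alpha cell genes gave 3 rises and 2 falls among 12 (camera adjusted p = 0.94), delta cell genes 1 and 2 among 6 (camera adjusted p = 0.45), and Schwann cell genes 3 and 0 among 8 (camera adjusted p = 0.11). Without male 44% fat replicate 3, 1 Schwann cell gene rose. Of 10 adipocyte genes only 3 were tested, without Adipoq or Plin1, and 2 of the 3 rose (camera adjusted p = 0.1). With library totals 1 adipocyte gene, 0 delta cell genes and 0 Schwann cell genes rose. By edgeR, 0 genes passed the threshold among 4 gamma and epsilon cell genes (camera adjusted p = 0.96), 6 Reg family genes (camera adjusted p = 0.3), 6 red blood cell genes (camera adjusted p = 0.49) and 16 immediate early genes (camera adjusted p = 0.06). The largest falls included Cib3, a calcium-binding protein gene (chromosome 8, 72204335 to 72212837; -3.21, SE 0.3, adjusted p = 3.86e-09), and the potassium channel gene Kcnj12 (-2.20, SE 0.29, adjusted p = 6.43e-07). Siglec1, a sialic acid receptor of macrophages, was among the largest rises (2.59, SE 0.62, adjusted p = 0.00125).

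In NZO/HlLtJ females on 44% fat (n = 4 per diet), genes of cell division and of macrophages rose and most delta cell genes fell. Beta cell identity and exocytosis genes moved in both directions. Chgb rose by 1.38 (SE 0.24, adjusted p = 0.000168), and the prohormone convertase Pcsk1 by 0.68 (SE 0.17, adjusted p = 0.00456). The endoplasmic reticulum degradation factor Derl3 rose by 2.40 (SE 0.36, adjusted p = 2.77e-05) and the chaperone Hsp90b1 by 0.77 (SE 0.17, adjusted p = 0.00133). Aldh1a3, an aldehyde dehydrogenase used as a marker of failing beta cells, went from 49.7 ± 17.0 to 164 ± 59.4 CPM (1.72, SE 0.31, adjusted p = 0.000267). Males did not match this rise, by the interaction given below. As a mean over the sexes, the Aldh1a3 effect lost its call without NZO/HlLtJ male 10% fat replicate 1 (0.64, adjusted p = 0.0551). The somatostatin gene Sst fell by 0.68 (SE 0.16, adjusted p = 0.00247). In all, 3492 genes were called, 1902 higher and 1590 lower, against 860 higher and 500 lower with NZO/HlLtJ libraries alone and 606 higher and 883 lower with counts scaled to library totals, which moved the median of all genes from -0.005 to -0.217.

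Of 29 unfolded protein response genes in these females 14 rose and 1 fell (14 and 1 over the list alone; median 0.61, camera adjusted p = 2.1e-05, adjusted p = 0.46 with an estimated correlation). When counts were scaled to library totals, 6 rose and 1 fell. Of 31 cell cycle genes 29 rose (30 over the list alone; median 1.62, camera adjusted p = 8.6e-35), with an adjusted p = 0.034 with an estimated correlation. The ribonucleotide reductase Rrm2 (1.42, SE 0.17) and Kif11 (1.52, SE 0.2) were among them. Of 19 macrophage genes 17 rose (18 over the list alone; median 1.58, camera adjusted p = 1e-15, adjusted p = 0.2 with an estimated correlation). All but 1 of 6 delta cell genes fell (5 over the list alone; median -0.64, camera adjusted p = 0.00062, adjusted p = 0.25 with an estimated correlation), among them the ghrelin receptor Ghsr (-1.11, SE 0.21). Of 26 beta cell identity genes 4 rose and 4 fell (4 and 6 over the list alone; camera adjusted p = 0.17), or 0 and 2 with library totals. Of 16 circadian clock genes 5 fell (7 over the list alone; camera adjusted p = 0.0036, adjusted p = 0.2 with an estimated correlation), including Hlf (-0.95, SE 0.25). The exocytosis genes had a median of 0.10 (7 rose and 4 fell; camera adjusted p = 0.19), which turned to -0.12 with counts scaled to library totals (2 rose and 2 fell).

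In NZO/HlLtJ males on 44% fat (n = 3 per diet) the fall of beta cell genes was larger. Ins1 fell by 1.00 (SE 0.22, adjusted p = 0.000855), from 50700 ± 7990 to 25400 ± 10500 CPM. Slc2a2 fell by 1.66 (SE 0.26, adjusted p = 1.9e-05), Ucn3 by 1.97 (SE 0.26, adjusted p = 2.52e-06) and Gipr by 2.02 (SE 0.24, adjusted p = 6.13e-07). Cib3 fell from 1.63 ± 1.02 to 0.0484 ± 0.0425 CPM (adjusted p = 3.48e-08). The B cell receptor component Cd79a rose by 4.03 (SE 0.75, adjusted p = 0.000122). The count was 6518 genes, 3451 higher and 3067 lower, and 3243 genes without replicate 3 of the males on 44% fat, or 2733 when 4 libraries of other groups that carried transcripts of another strain were left out too. Scaling to library totals gave 2343 higher and 965 lower, and limma-trend gave 4034 higher and 2180 lower.

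By list, 25 of 26 beta cell identity genes fell in these males (26 over the list alone; median -1.03, camera adjusted p = 7.3e-19, adjusted p = 0.12 with an estimated correlation). Without replicate 3 of the males on 44% fat, 19 fell. Of 24 exocytosis genes 15 fell (18 over the list alone; median -0.49, camera adjusted p = 3.7e-06, adjusted p = 0.25 with an estimated correlation), such as the granule protein Chga (-0.90, SE 0.2), with 5 falls without that library and 4 with library totals. Of 22 genes normally repressed in mature beta cells 20 rose (22 over the list alone; median 1.51, camera adjusted p = 1.1e-14, adjusted p = 0.15 with an estimated correlation), and 18 rose without it. All 19 macrophage genes rose (19 over the list alone; median 2.12, camera adjusted p = 5.9e-20, adjusted p = 0.12 with an estimated correlation), with C1qc up by 2.31 (SE 0.29). Of 16 lymphocyte and plasma cell genes 12 rose (15 over the list alone; camera adjusted p = 5.9e-06, adjusted p = 0.42 with an estimated correlation), and 4 rose without replicate 3 and 7 with library totals. Of 31 cell cycle genes 26 rose (28 over the list alone; camera adjusted p = 2.4e-13, adjusted p = 0.16 with an estimated correlation), and 16 rose without it. Acadl, an enzyme of fatty acid oxidation (1.03, SE 0.16, adjusted p = 1.72e-05), was among 12 genes that rose of 26 on its list (12 over the list alone; camera adjusted p = 0.011, adjusted p = 0.5 with an estimated correlation), and 6 rose without it.

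**Figure D3:**
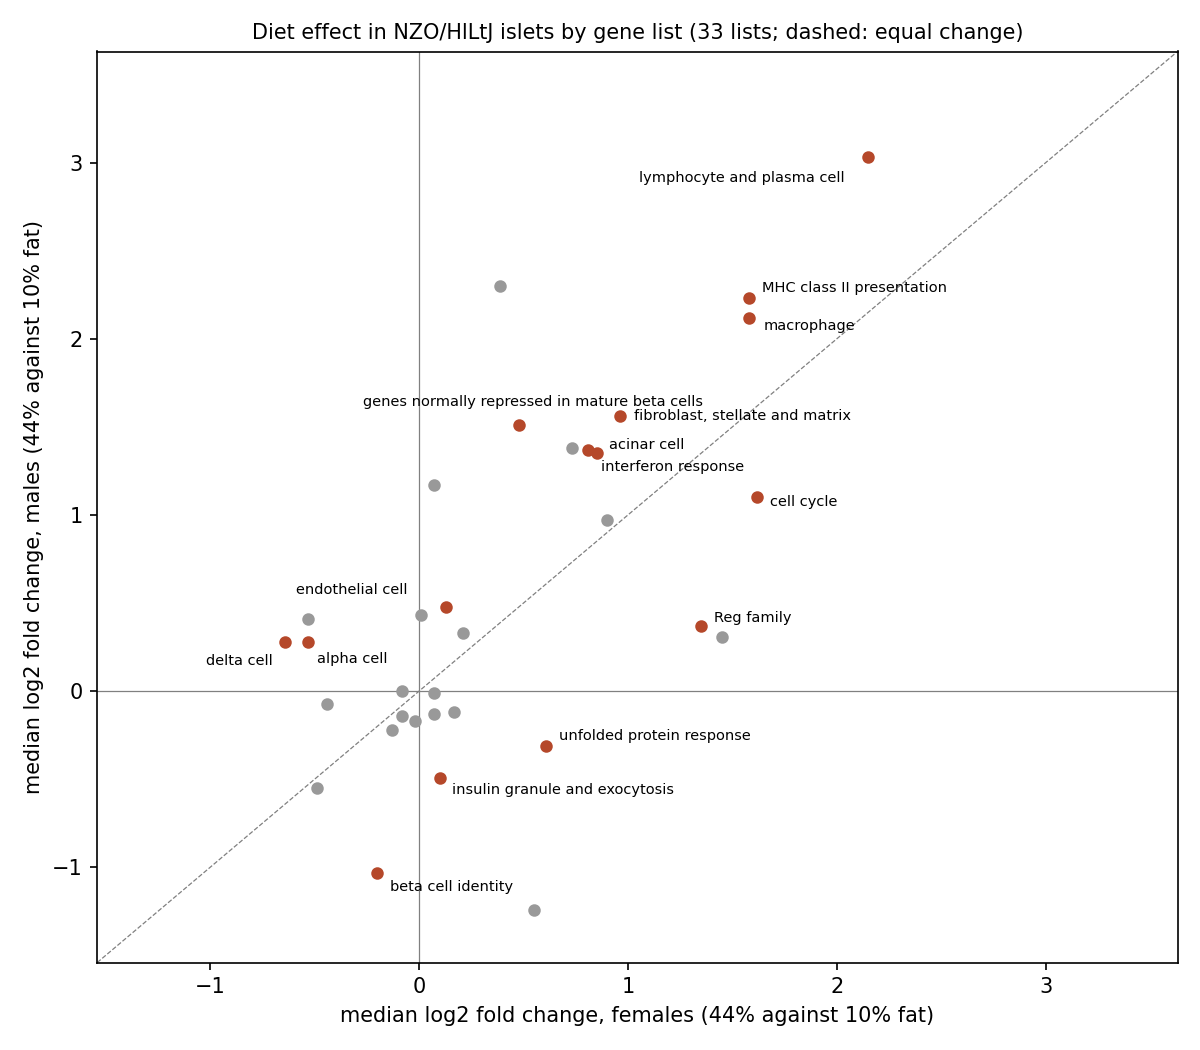
Median log2 fold change (44% against 10% fat) of the 33 gene lists in NZO/HlLtJ females (horizontal axis, n = 4 per diet) and males (vertical axis, n = 3 per diet), with equal change as a dashed line. Beta cell identity genes had a median of -0.20 in females and -1.03 in males.

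The diet effects of the 2 sexes were tested against each other as an interaction (male minus female effect), whose count of genes varied widely between models. It was -1.61 for Ins1 (SE 0.3, adjusted p = 0.00116), -1.59 for Ucn3 (SE 0.34, adjusted p = 0.0036), -1.51 for Pcsk1 (SE 0.26, adjusted p = 0.000522) and -2.48 for Derl3 (SE 0.53, adjusted p = 0.00375). It was -1.99 for Aldh1a3 (SE 0.47, adjusted p = 0.00749), or -1.73 (adjusted p = 0.0597) without NZO/HlLtJ male 44% fat replicate 3. Of 26 beta cell identity genes 20 had a lower interaction (23 over the list alone; median -1.04, camera adjusted p = 1.4e-18, adjusted p = 0.23 with an estimated correlation). There were 6 without that library and 2 with counts scaled to library totals. Of 29 unfolded protein response genes 14 were lower (16 over the list alone, with 1 higher; median -0.92, camera adjusted p = 6.4e-08, adjusted p = 0.51 with an estimated correlation), with 4 lower without it and 3 with library totals. In all 2030 genes were called, 897 higher and 1133 lower, against 331 without that library, 1104 without female 44% fat replicate 2 and 1297 without male 10% fat replicate 2. It was 134 with NZO/HlLtJ libraries alone and 213 without the 5 libraries that carried transcripts of another strain, that library among them. The split was 1152 higher and 927 lower with RLE, 1499 and 1149 with DESeq2, 1497 and 915 with limma-trend, and 206 and 54 with library totals, which moved the median of all genes from -0.001 to 0.157. The sexes shared 892 rises (323 expected by chance) and 675 falls (240 expected), and 136 genes went in opposite directions. Series 80 of the labels held females on 10% fat and males on 44% fat, and series 89 females on 44% fat and males on 10% fat. The interaction is thus partly confounded with the number series.

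Tested against C57BL/6J, the diet effect in NZO/HlLtJ was lower for mature beta cell genes and higher for immune and dividing cell genes. The interaction was -1.04 for Slc2a2 (SE 0.23, adjusted p = 0.00211), -1.10 for Ucn3 (SE 0.23, adjusted p = 0.00116), 1.93 for C1qc (SE 0.25, adjusted p = 9.65e-06) and 0.82 for the replication gene Mcm6 (SE 0.14, adjusted p = 0.0002). It was below 0 for 15 of 26 beta cell identity genes (16 over the list alone; median -0.63, camera adjusted p = 2.4e-11, adjusted p = 0.16 with an estimated correlation). It was above 0 for 19 of 19 macrophage genes (19 over the list alone; median 1.70, camera adjusted p = 5.2e-20, adjusted p = 0.15 with an estimated correlation). For the cell cycle 16 of 31 genes were above 0 (23 over the list alone; camera adjusted p = 3.3e-11, adjusted p = 0.16 with an estimated correlation), with 10 without NZO/HlLtJ male 44% fat replicate 3, 25 without male 10% fat replicate 3 and 1 with library totals. The count was 3814 genes, 1963 higher and 1851 lower, and 2333 without NZO/HlLtJ male 10% fat replicate 1. It was 1831 without the 5 libraries that carried transcripts of another strain. The split was 606 higher and 938 lower with library totals, which moved the median of all genes from -0.035 to -0.243, and 2576 and 1485 with limma-trend.

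Against CAST/EiJ the interaction was -1.02 for Slc30a8 (SE 0.17, adjusted p = 9.85e-05) and -0.84 for the endocrine factor Isl1 (SE 0.15, adjusted p = 0.000147). It was 2.11 for the lysosomal macrophage gene Cd68 (SE 0.28, adjusted p = 9.38e-06) and 1.31 for Kif11 (SE 0.21, adjusted p = 4.83e-05). It was below 0 for 17 of 26 beta cell identity genes (18 over the list alone; camera adjusted p = 1.3e-11, adjusted p = 0.22 with an estimated correlation). For the cell cycle it was above 0 for 29 of 31 genes (29 over the list alone; camera adjusted p = 1.5e-21, adjusted p = 0.12 with an estimated correlation). It was above 0 for all 19 macrophage genes too (19 over the list alone; camera adjusted p = 2.5e-19, adjusted p = 0.12 with an estimated correlation). In all 5209 genes were called, 2638 higher and 2571 lower, with 942 and 1685 under library totals, which moved the median of all genes from -0.005 to -0.233, and 3236 and 2020 under limma-trend. Of the CAST/EiJ females on 44% fat, 3 libraries carried transcripts of another strain. Without them and 2 such libraries of the other strains 2898 genes were called, 1087 higher and 1811 lower.

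In C57BL/6J few genes were called for the diet. As a mean over the sexes (n = 8 per diet) Kif11 rose by 0.99 (SE 0.14, adjusted p = 0.000482). In males it went from 1.23 ± 0.215 to 3.24 ± 0.774 CPM (1.39, SE 0.2, adjusted p = 0.000598, n = 4 per diet). The hormone genes gave 0.00 for Ins1 (SE 0.14), 0.06 for Ins2 (SE 0.13) and 0.15 for Gcg (SE 0.16), each with an adjusted p of 1. Of 31 cell cycle genes 2 rose in the mean over the sexes (20 over the list alone; median 0.57, camera adjusted p = 5.2e-27, adjusted p = 0.11 with an estimated correlation, fry adjusted p = 0.15). In males 3 rose (22 over the list alone; median 0.95, camera adjusted p = 5.8e-30, adjusted p = 0.071 with an estimated correlation). With library totals 1 rose in each. Camera also called the interferon response upward (adjusted p = 0.011) and 4 lists downward, namely acinar cells (0.0012), oxidative phosphorylation (0.0022), the unfolded protein response (0.012) and fibroblasts with matrix (0.037). In these 5 lists 0 genes passed the threshold by edgeR, and 0 lists were called with an estimated correlation or by fry. The count was 5 genes, all higher, of which 4 also rose in NZO/HlLtJ (0.926 expected by chance), and DESeq2 called 49, limma-voom 1 and limma-trend 2. It ranged from 1 to 26 when single libraries were left out (1 without female 10% fat replicate 4, 26 without male 44% fat replicate 3). In males 9 genes were called, 45 by DESeq2, 1 by limma-voom and 1 by limma-trend, and 1 to 24 without single libraries (1 without male 10% fat replicate 3, 24 without male 44% fat replicate 3). In females edgeR called 0 genes, with 658 at an unadjusted p under 0.05, DESeq2 called 6, limma-voom 0 and limma-trend 0. The diet-by-sex interaction gave 0 genes by edgeR, with 805 at an unadjusted p under 0.05, 8 by DESeq2, 0 by limma-voom and 1 by limma-trend.

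In CAST/EiJ the called genes were largely genes with no or low counts in this strain. Whether their transcripts are absent or their reads failed to match the genome was not tested. All 9 genes called as a mean over the sexes (n = 8 on 44% fat, n = 7 on 10% fat) were higher on 44% fat. Of these, 3 had a median under 0.1 CPM in the other CAST/EiJ groups and 6 were more than 8-fold lower than in another strain on 10% fat. An example is Rpl19-ps11, a ribosomal protein pseudogene (2.25, SE 0.38, adjusted p = 0.00455), which gave -0.03 without the 5 libraries that carried transcripts of another strain. In females (n = 4 per diet) 52 genes were called, 45 higher and 7 lower, against 86 higher and 76 lower by DESeq2. Of the 52, 23 had a median under 0.1 CPM and 17 were more than 8-fold lower in CAST/EiJ by the same measures. The other 12 included Socs2, a cytokine signalling inhibitor induced by prolactin (0.85, SE 0.16, adjusted p = 0.00435). It belongs to the serotonin and prolactin list, in which 1 of 9 genes rose (3 over the list alone; camera adjusted p = 0.0059, adjusted p = 0.39 with an estimated correlation), and 2 rose with library totals. The hormone genes gave -0.08 for Ins1 (SE 0.14, adjusted p = 0.939) and -0.24 for Gcg (SE 0.17, adjusted p = 0.789) as means over the sexes. The count in females was 407 without female 10% fat replicate 2, 29 without female 44% fat replicate 1, and 1 without the libraries that carried transcripts of another strain, which leaves 1 library in the females on 44% fat. For the mean effect the split was 14 higher and 2 lower with RLE, 33 and 9 with DESeq2, 1 and 1 with limma-voom, and 3 and 2 with limma-trend. The count was 65 without female 10% fat replicate 2, 26 without female 44% fat replicate 3, and 1 without those libraries.

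**Figure D4:**
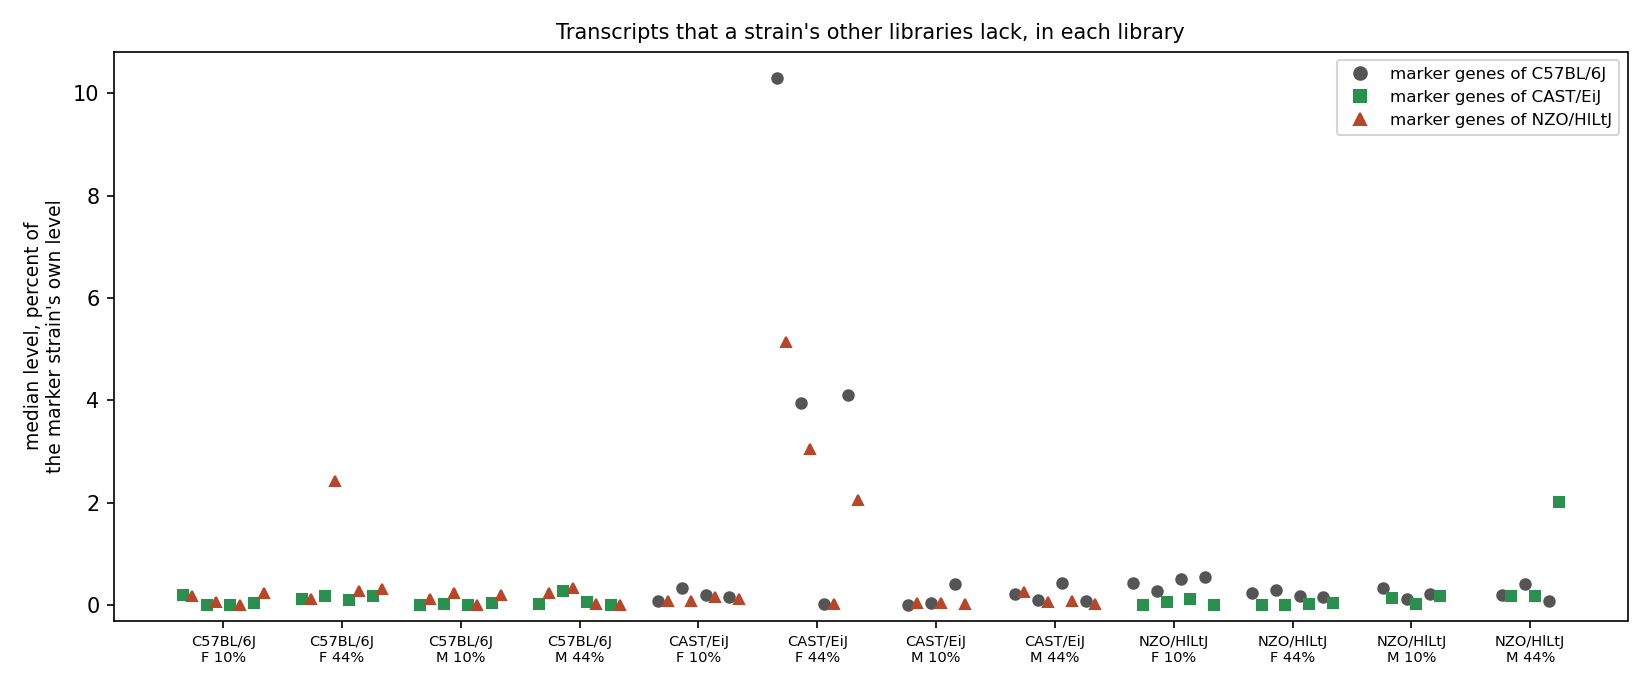
Median level of marker genes of another strain in each library, in percent of the marker strain's own level, for 3 strains, both sexes and both diets. Each library has 1 point per other strain, over genes with a median under 0.1 CPM in the other groups of its own strain. In CAST/EiJ females on 44% fat the median over 18 C57BL/6J markers was 10.3% in replicate 1 and 0.0169% in replicate 3.

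In CAST/EiJ males (4 libraries on 44% fat and 3 on 10% fat) 2 genes were called, 1 higher and 1 lower. The range was 0 to 13 when single libraries were left out (0 without male 10% fat replicate 3, 13 without male 10% fat replicate 2). The diet-by-sex interaction in CAST/EiJ gave 6 genes, all lower. DESeq2 gave 1 higher and 27 lower, limma-trend 1 lower and limma-voom 0 (506 genes at an unadjusted p under 0.05, against 1002 by edgeR). It ranged from 1 to 19 without single libraries (1 without male 10% fat replicate 3, 19 without female 44% fat replicate 3), and 0 were called without the libraries that carried transcripts of another strain. The difference of the diet effect between CAST/EiJ and C57BL/6J was called for 4 genes, all higher. By the same measures 3 of them had a median under 0.1 CPM in CAST/EiJ and 1 was more than 8-fold lower there. This difference varied with single libraries. It was called for 1 to 17 genes without single libraries (1 without CAST/EiJ female 10% fat replicate 4, 17 without CAST/EiJ female 44% fat replicate 3). Here 0 of 31 cell cycle genes passed the threshold (6 were lower over the list alone; median -0.55, camera adjusted p = 1.8e-14, adjusted p = 0.56 with an estimated correlation).

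On 10% fat, NZO/HlLtJ islets (n = 7) differed from C57BL/6J islets (n = 8) in endocrine, vascular and mitochondrial genes. Aldh1a3 was higher by 4.97 (SE 0.26, adjusted p = 1.5e-17), at 49.7 ± 17.0 CPM in females and 152 ± 29.8 CPM in males against 1.91 ± 0.286 and 4.01 ± 1.63 CPM. The glucagon gene Gcg was lower by 1.07 (SE 0.17, adjusted p = 3.9e-06), Sst by 0.82 (SE 0.12, adjusted p = 3.68e-07), Slc2a2 by 0.67 (SE 0.17, adjusted p = 0.0011) and Isl1 by 0.89 (SE 0.1, adjusted p = 6.22e-09). The antiviral gene Mx1, which is defective in C57BL/6J, was higher by 7.06 (SE 0.44, adjusted p = 4.04e-15). Of 15 endothelial genes 14 were higher (14 over the list alone; median 0.54, camera adjusted p = 5.5e-08, adjusted p = 0.47 with an estimated correlation). Of 20 fibroblast and matrix genes 18 were higher and 1 lower (18 and 1 over the list alone; camera adjusted p = 1.9e-07, adjusted p = 0.59 with an estimated correlation), such as the pericyte gene Rgs5 (1.58, SE 0.098). Of 32 oxidative phosphorylation genes 26 were higher (28 over the list alone; median 0.30, camera adjusted p = 4.2e-09, adjusted p = 0.59 with an estimated correlation). All 6 delta cell genes were lower (6 over the list alone; camera adjusted p = 0.00095, adjusted p = 0.47 with an estimated correlation). In all 8903 genes were called, 4632 higher and 4271 lower.

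CAST/EiJ (n = 7) also differed from C57BL/6J on 10% fat, with 9742 genes called, 4948 higher and 4794 lower. The sources used here do not say whether strain variants were allowed for when reads were matched to the genome, and low counts of a gene in CAST/EiJ or NZO/HlLtJ can also arise from reads that failed to match. Aldh1a3 was higher by 2.45 (SE 0.24, adjusted p = 6.7e-11) and Ins1 by 0.55 (SE 0.14, adjusted p = 0.00147), and Gcg gave 0.18 (SE 0.17, adjusted p = 0.417). Interferon response genes were lower, with 21 of 32 lower and 4 higher (22 and 4 over the list alone; median -0.84, camera adjusted p = 0.0023, adjusted p = 0.96 with an estimated correlation). Examples are the RNA sensor Ifih1 (-2.34, SE 0.14, adjusted p = 1.7e-17) and Oas1a (-2.86, SE 0.21, adjusted p = 1.56e-14). On the fatty acid synthesis list 7 of 18 genes were higher and 1 lower (camera adjusted p = 0.081, fry adjusted p = 3.3e-07). The desaturase Fads2 (1.28, SE 0.1, adjusted p = 1.31e-13) and the elongase Elovl6 (0.93, SE 0.083, adjusted p = 2.52e-12) were among those higher.

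Between NZO/HlLtJ and CAST/EiJ on 10% fat (n = 7 each), 11120 genes were called, 5596 higher and 5524 lower in NZO/HlLtJ. Interferon response genes were higher in NZO/HlLtJ, 29 of 32 with 2 lower (29 and 2 over the list alone; median 1.56, camera adjusted p = 5.3e-08, adjusted p = 1 with an estimated correlation). The incretin receptor gene Gipr was lower by 1.28 (SE 0.15, adjusted p = 6.48e-09), Trpm5 by 2.02 (SE 0.16, adjusted p = 3.14e-13) and Slc2a2 by 1.20 (SE 0.17, adjusted p = 2.32e-07). Of 29 unfolded protein response genes 20 were higher (20 over the list alone; median 0.55, camera adjusted p = 0.0013, adjusted p = 1 with an estimated correlation), such as the stress sensor Ern1 (0.76, SE 0.09).

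Males and females on 10% fat (n = 10 and n = 12) differed in 185 genes, 53 higher and 132 lower in males. Sex is partly confounded with the number series here, since in NZO/HlLtJ on 10% fat series 80 held only females and series 89 only males. Besides Ddx3y (14.11, SE 0.31) and Xist (-10.62, SE 0.66), the complement gene C7 was higher in males by 4.21 (SE 0.32, adjusted p = 6.53e-12) and Aldh1a3 by 1.23 (SE 0.19, adjusted p = 0.000257). Gcg was lower in males by 0.67 (SE 0.14, adjusted p = 0.0117). So were the retinol carrier Rbp4 by 0.57 (SE 0.11, adjusted p = 0.00594) and the imprinted gene Peg10 by 1.33 (SE 0.17, adjusted p = 9.83e-06). Of 12 alpha cell genes 5 were lower and 1 higher (9 and 1 over the list alone; median -0.51, camera adjusted p = 2e-09, adjusted p = 0.13 with an estimated correlation, fry adjusted p = 0.013), and 0 were called with library totals. The count was 108 without C57BL/6J male 10% fat replicate 1, 123 without C57BL/6J male 10% fat replicate 3, 120 without CAST/EiJ female 10% fat replicate 3, and 107 without CAST/EiJ male 10% fat replicate 2. It was 300 without NZO/HlLtJ male 10% fat replicate 1 and 90 without NZO/HlLtJ male 10% fat replicate 3. It was 40 higher and 14 lower with library totals, which moved the median of all genes to 0.124, and 17 higher and 87 lower with limma-voom.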

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

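The tests of explanations for the 3 patterns weighed here, and the predictions for other splits of the samples for the diet effects and for the diet-by-sex interaction in NZO/HlLtJ, were written after those results were seen. Within groups of 4 libraries, a library was noted when its gap to the nearest of the others exceeded Dixon's 95% limit, as a share of the range of its group. This gave 12 libraries in 135 tests of 15 measures, where chance gives 6.75.

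The first pattern is the presence of transcripts that CAST/EiJ lacks in libraries of CAST/EiJ females on 44% fat. A response to the diet is argued against by replicate 3 of the same group, where the median over the marker genes was 0.0169% of the C57BL/6J level. A chromosome segment of another strain carried by the animal would give a large part or all of the C57BL/6J level on its chromosome and none elsewhere. In replicate 1 the 18 markers lay on 9 chromosomes with medians of 9.19 to 17%. RNA or reads of another strain mixed in may account for the pattern, since all 18 markers were present in replicate 1, with a median of 10.3% (quartiles 9.26 and 14.2), and replicates 2 and 4 had medians of 3.94% and 4.11%. Which strain was the source in replicate 2 stays open. There 2 C57BL/6J markers absent in NZO/HlLtJ were at 0.995%, and 2 NZO/HlLtJ markers absent in C57BL/6J at 2.25%. Low counts of the markers in the other CAST/EiJ libraries may come from absent transcripts or from CAST/EiJ reads that failed to match the genome, which was not tested. No biological explanation beyond the diet and such a segment was tested.

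The second pattern is the fall of beta cell identity genes in NZO/HlLtJ males on 44% fat, in 25 of 26 genes. A lower share of beta cells alone would raise markers of all other cell types alike. The lower quartile of the lymphocyte and plasma cell genes instead exceeded the upper quartile of the endothelial genes by 1.96 (log2). This pair was the most distant among the larger lists, so it does not show whether the beta cell share also fell. Median changes were 0.28 for alpha, 0.28 for delta, 0.41 for gamma and epsilon and 0.48 for endothelial cell genes. They were 1.17 for Schwann cell, 1.38 for duct, 1.56 for fibroblast and matrix, 2.12 for macrophage and 3.03 for lymphocyte and plasma cell genes. The smaller, similar rises would also follow from a lower beta cell share. Exocrine tissue as the whole cause is argued against by 24 genes that still fell with an acinar score in the model, and 1 library that stands apart by 19 that fell without male 44% fat replicate 3. A change within beta cells under the diet may account for the fall, as a hypothesis from the same data. A lower beta cell share together with a gain of particular immune and stromal cells stays open, since bulk RNA holds no measure of cell number.

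The third pattern is the larger number of calls for the diet in NZO/HlLtJ than in the other strains. The number series of the labels as batches is argued against by 7775 genes called with that series as a factor. In NZO/HlLtJ the series is balanced over the diets for both sexes together. Within each sex it is not, since series 80 and 89 lie on opposite diets, so single-sex effects are partly confounded with it. A smaller spread between NZO/HlLtJ libraries was not found. The median SD of log2 CPM within groups was 0.293 in NZO/HlLtJ, 0.242 in C57BL/6J and 0.26 in CAST/EiJ. It was 0.261 in NZO/HlLtJ females (0.233 and 0.256 in the other strains) and 0.314 in NZO/HlLtJ males (0.239 and 0.241). The main model shared its estimate of spread over all groups, so a smaller spread could not by itself have raised the counts. A larger one can, since the shared estimate may be too small for NZO/HlLtJ. With NZO/HlLtJ libraries alone the counts in females and for diet by sex fell. The count of the mean effect was 5081 or more under the models that kept all NZO/HlLtJ libraries. A response to the diet that is larger in NZO/HlLtJ may account for the counts, and how the strains differed in body weight or glycemia was not analysed here.

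Interaction tests of the diet effect called 3814 genes between NZO/HlLtJ and C57BL/6J, 5209 between NZO/HlLtJ and CAST/EiJ and 4 between CAST/EiJ and C57BL/6J. Between the sexes the test called 2030 genes in NZO/HlLtJ and 6 in CAST/EiJ. For these last 2 counts and for the 4 genes, chance cannot be excluded (6 of 100, 40 of 99 and 7 of 100 splits as large), and without single libraries they ranged from 331 to 2556, 1 to 19 and 1 to 17. With NZO/HlLtJ libraries alone the 2030 became 134. By fry, 10 gene lists differed between NZO/HlLtJ and C57BL/6J, 13 between NZO/HlLtJ and CAST/EiJ, and 5 between the sexes in NZO/HlLtJ. By camera with an estimated correlation 0 lists were called in each of these 3 comparisons, against 15, 14 and 16 at the preset correlation.

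The acinar share of the counts stood far from the others in C57BL/6J male 44% fat replicate 1 (16.6%, others 3.14 to 3.8%), CAST/EiJ female 10% fat replicate 4 (44.3%, others 1.6 to 7.99%) and NZO/HlLtJ female 10% fat replicate 2 (9.87%, others 2.16 to 3.06%). Lymphocyte and plasma cell transcripts did so in C57BL/6J male 44% fat replicate 2 (52.5 CPM, others 6.25 to 13.2), CAST/EiJ female 44% fat replicate 1 (9.78 CPM, others 7.32 to 7.58) and CAST/EiJ male 44% fat replicate 1 (88.5 CPM, others 5.42 to 7.97). Aldh1a3 did so in CAST/EiJ male 44% fat replicate 4 (24.1 CPM, others 15.8 to 16.8) and NZO/HlLtJ female 10% fat replicate 3 (24.3 CPM, others 55.7 to 60.5). Nnt did so in C57BL/6J female 10% fat replicate 3 (35.6 CPM, others 29.9 to 30.4) and NZO/HlLtJ female 44% fat replicate 4 (67.5 CPM, others 112 to 113). Ucn3 did so in C57BL/6J female 10% fat replicate 4 (254 CPM, others 340 to 353), and Sst in NZO/HlLtJ female 10% fat replicate 4 (2540 CPM, others 2210 to 2240). Groups of 3 libraries were outside these tests. In CAST/EiJ males on 10% fat, replicate 3 held 164 CPM of lymphocyte and plasma cell transcripts, against 7.37 and 5.27 CPM in replicates 1 and 2.

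Other splits of the samples were refitted for the count of each comparison. The limit was a share of splits under 0.05, not adjusted for the 19 comparisons. By it chance can be excluded for the diet effect in NZO/HlLtJ (7270 genes, highest other split 5378, 1 of 94 splits as large) and in NZO/HlLtJ females (3492, highest other 810, 1 of 35). It can be excluded for the diet-by-strain interactions of NZO/HlLtJ with C57BL/6J (3814, highest other 1793, 1 of 100) and with CAST/EiJ (5209, highest other 1380, 1 of 100). The same holds for the strain differences between NZO/HlLtJ and C57BL/6J (8903, highest other 4268, 1 of 99), CAST/EiJ and C57BL/6J (9742, highest other 5004, 1 of 98) and NZO/HlLtJ and CAST/EiJ (11120, highest other 9732, 1 of 97). The share was also under 0.05 for the mean diet effect in C57BL/6J (5, highest other 15, 3 of 96) and the sex difference (185, highest other 346, 3 of 100). In these comparisons other splits called more genes than the real groups, so chance is not firmly excluded.

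Chance cannot be excluded for the count of the diet-by-sex interaction in NZO/HlLtJ (2030, highest other 5092, 6 of 100), with the sexes reassigned within each diet. Nor can it be for the diet effect in CAST/EiJ (9, highest other 159, 13 of 94), in CAST/EiJ females (52, highest other 329, 4 of 35) or in CAST/EiJ males (2, highest other 306, 22 of 35). The same holds for the interactions of diet with strain between CAST/EiJ and C57BL/6J (4, highest other 16, 7 of 100) and of diet with sex in CAST/EiJ (6, highest other 415, 40 of 99). Splits decide nothing where edgeR called 0 genes, since each split then has as many, as in C57BL/6J females (highest other 2, 35 of 35, 658 genes at an unadjusted p under 0.05, 6 called by DESeq2) and for diet by sex in C57BL/6J (highest other 972, 99 of 99, 805 genes, 8 by DESeq2). Other splits gave several times the real count in CAST/EiJ comparisons, in C57BL/6J as a mean over the sexes and in diet-by-sex interactions. These may reflect a structure of the samples other than the groups compared, which was not tested. For NZO/HlLtJ males the 10 splits are too few for a share under 0.05 (6518, highest other 1149, 1 split as large).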

How the results depend on the processing

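Models without 5 libraries that carried transcripts of another strain and without 3 libraries with high lymphocyte markers were chosen after the results were seen, and the other models were chosen before. Calls for the diet in NZO/HlLtJ numbered 5081 to 7775 under the models that kept all its libraries, and 5763 to 11399 for the strain differences. The small counts in C57BL/6J and CAST/EiJ moved by several fold, and the diet-by-sex count in NZO/HlLtJ moved from 2030 to 134 with its libraries alone. The cause was not tested for any of these changes, apart from the smaller number of samples where libraries were left out. At 1 CPM a gene rests on about the library total in M (57.2 to 110) times the TMM factor (0.486 to 1.178) in counts. Genes far below 1 CPM are limited by depth. No paired analysis was possible because replicate numbers only follow the order of the series.

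With DESeq2 the diet effect was called for 49 genes in C57BL/6J, 42 in CAST/EiJ, 6 in C57BL/6J females, 45 in C57BL/6J males, 162 in CAST/EiJ females and 4 in CAST/EiJ males. The CAST/EiJ minus C57BL/6J interaction gave 21, the diet-by-sex interaction 8 in C57BL/6J and 28 in CAST/EiJ, and the sex difference 376. With limma-voom the counts were 1 in C57BL/6J, 2 in CAST/EiJ, 1 in C57BL/6J males and 104 for sex. It called 0 in CAST/EiJ females (1504 at an unadjusted p under 0.05), for CAST/EiJ minus C57BL/6J (556) and for diet by sex in CAST/EiJ (506). With limma-trend they were 2 in C57BL/6J, 5 in CAST/EiJ, 1 in C57BL/6J males, 18 in CAST/EiJ females, 0 for CAST/EiJ minus C57BL/6J (705 unadjusted), and 1 each for diet by sex in C57BL/6J and CAST/EiJ. Of the genes, 9930111J21Rik2 and 9930111J21Rik1 turned to 0.23 and 0.41 in the NZO/HlLtJ minus CAST/EiJ interaction.

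With library totals the diet effect gave 3 genes in C57BL/6J, 1 in C57BL/6J males, 1 in CAST/EiJ males, 1489 in NZO/HlLtJ females and 3308 in NZO/HlLtJ males. The interactions gave 1544 (NZO/HlLtJ minus C57BL/6J), 2627 (NZO/HlLtJ minus CAST/EiJ) and 260 (diet by sex in NZO/HlLtJ), the NZO/HlLtJ minus C57BL/6J strain difference 5763 and sex 54. RLE gave 16 in CAST/EiJ, and no filter gave 3 in C57BL/6J males. The legacy method gave 1 in C57BL/6J males, 0 in CAST/EiJ males (521 unadjusted) and 2 for diet by sex in CAST/EiJ. The number series as a factor gave 9 in C57BL/6J, 2 in C57BL/6J males, 0 in CAST/EiJ males (545 unadjusted) and 2 for diet by sex in CAST/EiJ. The acinar score gave 4 in CAST/EiJ, 5 in C57BL/6J males, 1 for CAST/EiJ minus C57BL/6J and 2 for diet by sex in CAST/EiJ.

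Models of single strains pool less information on spread and use only the spread of that strain. They gave 1 in C57BL/6J and 1 in its males, 1360 in NZO/HlLtJ females and 134 for diet by sex in NZO/HlLtJ. By edgeR on CAST/EiJ alone, 0 genes were called for the mean effect (1463 unadjusted), females (1774), males (362) and diet by sex (629), and on C57BL/6J and CAST/EiJ 0 were called for their interaction (823). Without the 3 libraries with high lymphocyte markers the counts were 1 in C57BL/6J, 3 in CAST/EiJ, 1 in C57BL/6J males, 0 in CAST/EiJ males (1166 unadjusted), 1 for CAST/EiJ minus C57BL/6J and 1 for diet by sex in CAST/EiJ. Without the 5 libraries the lone library left in CAST/EiJ females on 44% fat is assumed to vary like the other groups. The counts were then 1 in C57BL/6J, 1 in CAST/EiJ, 1 in CAST/EiJ females, 2733 in NZO/HlLtJ males, 1831 for NZO/HlLtJ minus C57BL/6J, 1 for CAST/EiJ minus C57BL/6J, 2898 for NZO/HlLtJ minus CAST/EiJ, 0 for diet by sex in CAST/EiJ (690 unadjusted) and 213 in NZO/HlLtJ. Values that turned were Rpl9-ps6 (-1.18) and Rpl19-ps11 (-0.03) in CAST/EiJ, Fam213b (0.00), 9930111J21Rik1 (0.00), 9930111J21Rik2 (-1.73), Rpl9-ps6 (-2.98) and Tmem254b (-2.97) in CAST/EiJ females, Mndal (0.00) and Xist (-0.07) in NZO/HlLtJ males, Rpl9-ps6 (1.36) in NZO/HlLtJ minus CAST/EiJ, and Rpl19-ps11 (0.61) in diet by sex in CAST/EiJ. Of the 212 list calls by camera 1 was left with an estimated correlation, and fry made 115.

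With each library left out in turn, the diet effect ranged from 1 to 26 genes in C57BL/6J, 7 to 65 in CAST/EiJ, 5823 to 8275 in NZO/HlLtJ, 0 to 0 in C57BL/6J females, 1 to 24 in C57BL/6J males, 29 to 407 in CAST/EiJ females, 0 to 13 in CAST/EiJ males, 2382 to 3885 in NZO/HlLtJ females and 3243 to 7243 in NZO/HlLtJ males. The interactions ranged from 2333 to 5433 (NZO/HlLtJ minus C57BL/6J), 1 to 17 (CAST/EiJ minus C57BL/6J), 3854 to 6509 (NZO/HlLtJ minus CAST/EiJ), and for diet by sex 0 to 1 in C57BL/6J, 1 to 19 in CAST/EiJ and 331 to 2556 in NZO/HlLtJ. The strain differences ranged from 7464 to 9519, 9218 to 9654 and 10442 to 11360, and sex from 90 to 300. Without NZO/HlLtJ male 44% fat replicate 3, Mndal turned to 0.00 and Xist to -0.08 in NZO/HlLtJ males, where single libraries gave at most 5.91 and 6.06.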

Other observations

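The measure of transcripts from another strain was chosen after the results were seen, and the list tests given here were fixed before. On 10% fat NZO/HlLtJ also had higher levels of stress and defence genes than C57BL/6J. Of 29 unfolded protein response genes 17 were higher (17 over the list alone; median log2 difference 0.47, camera adjusted p = 0.00028, and adjusted p = 0.59 with an estimated correlation), such as the co-chaperone Dnajb11 (0.86, SE 0.17, adjusted p = 9.22e-05) and the secreted chaperone-associated factor Manf (0.88, SE 0.17, adjusted p = 4.04e-05). Of 15 antioxidant genes 11 were higher and 1 lower (11 and 1 over the list alone; camera adjusted p = 0.0012, and adjusted p = 0.47 with an estimated correlation). Of 31 cell cycle genes 24 were higher (25 over the list alone, with 1 lower; median 0.87, camera adjusted p = 0.0002, and adjusted p = 0.65 with an estimated correlation), and in CAST/EiJ 24 were higher and 3 lower than in C57BL/6J (24 and 3 over the list alone; median 0.99, camera adjusted p = 0.00071, and adjusted p = 0.96 with an estimated correlation). Kif11, which rose on 44% fat in C57BL/6J males, was at 1.85 ± 0.409 CPM in NZO/HlLtJ females on 10% fat (n = 4) and 2.60 ± 0.58 CPM in males (n = 3).

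In NZO/HlLtJ males on 44% fat all 3 adipocyte genes tested, Plin4, Fabp4 and Pck1, rose (3 over the list alone; median 2.30, camera adjusted p = 0.041, and adjusted p = 0.25 with an estimated correlation), and 1 rose without male 44% fat replicate 3. The other listed adipocyte genes, Adipoq, Plin1, Cidec, Lep, Cfd, Retn and Car3, were not tested. Of 20 fibroblast and matrix genes 18 rose (18 over the list alone; median 1.56, camera adjusted p = 2.6e-12, and adjusted p = 0.16 with an estimated correlation). Of 16 circadian clock genes 3 were lower in males than in females on 10% fat (6 lower and 2 higher over the list alone; camera adjusted p = 0.0014, and adjusted p = 0.15 with an estimated correlation), including Dbp (-0.96, SE 0.2, adjusted p = 0.0108) and Tef (-0.58, SE 0.12, adjusted p = 0.011), and 0 were called with library totals.

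Outside the CAST/EiJ females, transcripts of another strain were found in C57BL/6J female 44% fat replicate 2, with a median of 2.43% of the NZO/HlLtJ level over 10 markers, all detected, and in NZO/HlLtJ male 44% fat replicate 3, with 2.01% of the CAST/EiJ level and 13 of 15 markers detected. The latter library also held the highest level of Xist among the male libraries, at 15.4 CPM.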
